A study of Bacillus subtilis with 6 samples.

How the data were processed

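Total RNA of Bacillus subtilis was measured on 6 two-colour spotted arrays, 3 of cultures without xylose and 3 of cultures with xylose, all taken at 60 min. Per the design text, cells grew in minimal arabinose medium, the culture was divided at the start, and xylose was given to one set to switch on a DNA endonuclease, an enzyme that cuts DNA. The labels do not name the enzyme or its cutting sites. On every array the sample was labelled with Cy5 (read at 635 nm) and a pooled reference RNA with Cy3 (read at 532 nm), so that no dye swap was made. No array held xylose-treated cells without the endonuclease, and effects of xylose and of the endonuclease were therefore not separable. The labels call the arrays of a set replicates without saying whether they came from separate cultures, and the p-values measure the spread between these samples, which may be partly technical.

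Per the file headers, the authors scanned the slides on a GenePix 4000B scanner and read the spots with GenePix Pro 3.0.6.90. The deposited intensity values used here were the median pixel brightness of each spot and of its local background in each channel, with no normalization. The authors' deposited log2 ratio in the same files was, per the file headers, the sample signal over the reference signal scaled by the summed signal of each channel, without background subtraction. The same sheets gave a low-intensity mark for spots with under 80% of pixels above background plus 1 SD, and 3 rounds of outlier removal. On all 6 arrays the deposited log2 values equalled the ratio of the signal columns up to 1 constant per array. The Cy5 signal equalled the mean pixel brightness times the number of pixels. The authors' ratios thus rest on another summary of the spots than the medians. The deposited value table of the series held 4507 rows per array, and its sorted values equalled the authors' log2 ratios with the sign turned (reference over sample) within 1e-05 on all 6 arrays. Its scale, centring and direction were thus settled, but its row identifiers matched no probe column, so the log2 ratios in the scanner files were used in its place. The medians of its columns were -0.13, 0.12 and 0.08 without xylose and 0.28, 0.27 and 0.03 with xylose, for replicates 1 to 3.

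Each array held 4624 spots, of which 117 were empty or Escherichia coli control spots, 4242 were probes of genes and 265 were probes of intergenic regions. Spot intensity was corrected with normexp (offset 50) in limma 3.58.1 under R 4.3.3, and the log2 ratio of Cy5 over Cy3 was normalized by loess within each array, with weight 0 for control spots and for the 91 spots that the scanner files mark as bad on every array. Control and bad spots were then left out, while spots marked as not found (176 to 225 per array) were kept. Probes of 1 gene were averaged. Of the 4089 genes on the array, 4050 were tested, those with values on at least 2 arrays of each group. For 85 genes with several probes, the fold changes of the probes differed by more than 1 log2 unit in 3 genes, of which xylA passed the threshold. Genes carry the names of the array design, some of them old. Their order along the chromosome came from a reference gene table that names its assembly but not the build of the array, so only gene order was used, for the 2974 genes (73.4%) whose symbols matched.

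The comparison of xylose with no xylose used lmFit and eBayes of limma with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. Fold changes are log2 values of xylose minus no xylose. Gene lists were compared with the other genes by camera in limma with an inter-gene correlation of 0.01, adjusted over 21 lists, and with an estimated correlation and with fry as alternatives. The lists were compiled from general knowledge of the organism. They cover the LexA (SOS) regulon, xylose and arabinose utilisation, carbon catabolite control, the SPbeta and PBSX prophages, the ICEBs1 and skin elements, the DnaA regulon, recombination and repair outside the LexA list, ribonucleotide reductase, purine and pyrimidine synthesis, competence, motility and chemotaxis, SigB general stress, heat shock, early sporulation, cell division, ribosomal proteins, and respiration with ATP synthase. The trend along the chromosome was the slope of each array's log2 ratio over gene order from dnaA to the terminus, compared by an exact two-sided permutation test, for which 3 against 3 arrays allow a smallest p of 0.1. To look at each dye apart, the normalized ratios and intensities were also put on a common scale (Aquantile in limma) and turned back into Cy5 and Cy3 log2 signals.

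Groups, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined, except for the additions named in the closing section. Genes named are the 10 largest rises and 10 largest falls past the threshold whose groups do not overlap, the LexA members past the threshold (at most 12) with recA, lexA, dinB, uvrA, uvrB, yneA and ruvA, all xylose utilisation genes, and up to 4 members with the smallest p of each other list. Where under 5 genes passed in a direction, the 5 with the smallest p were to be named as not having passed. Other genes that the text names were chosen after their values were seen, and are said to be.

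Alternatives were tried for background correction, loess, scaling between arrays, the authors' log2 ratios, dim genes, marked spots, genes with a value on all arrays, the variance model, array weights, a replicate block, and each array left out in turn. Median signal over background in Cy5 was 7.91 to 12.3, no probe had 50% or more of its pixels saturated, and the number of arrays limits the precision. The test was tried on simulated data with the spread of the real genes, in 20 runs with 200 of 4050 genes changed. It found 39.3% of changes of 0.5 log2 units, 83.4% of changes of 1, 90.6% of changes of 1.5 and 95.5% of changes of 2, and 5.97% of its calls were false. A list of 44 genes shifted by 0.3 log2 units was called by camera in 20 of 20 runs and an unshifted list in 1 of 20. The simulated genes were drawn independently of each other. These runs therefore do not show how often camera calls unshifted lists whose genes are correlated. The figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

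Per the file headers, the arrays were scanned in the order no-xylose 1, xylose 1, no-xylose 2, xylose 2, no-xylose 3, xylose 3, and the images of all no-xylose arrays lay at one end of the scanned area and those of all xylose arrays at the other. The place on the slide and the group cannot be told apart, and the files name no slide.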

Results

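Gene expression was measured in Bacillus subtilis cells grown in minimal arabinose medium, 60 min after part of the culture received xylose to switch on a DNA endonuclease. There were 3 arrays without xylose and 3 with xylose, each hybridised with Cy5-labelled sample RNA and a Cy3-labelled pooled reference RNA. Median spot brightness was 996 to 1956 in Cy5 and 967 to 1863 in Cy3, and 88.2% to 92.2% of probes lay above background in Cy5. Correlations of log2 ratios over the 4050 genes were 0.67 to 0.84 between no-xylose arrays and 0.46 to 0.82 between xylose arrays. The xylose replicate 3 array stood farthest from its group, with an SD of 0.309 log2 units around the group mean against 0.167 to 0.246 for the other arrays.

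The first comparison asked which transcripts differed between cells with and without xylose. Genes of xylose breakdown, the glucose permease gene ptsG and genes of the LexA-controlled SOS response to DNA damage led the list of higher transcripts. Among the rises were xylB, the xylulokinase gene (log2 fold 4.73 ± 0.15, SE), ptsG (4.47 ± 0.13), xynB, a xylosidase gene (4.43 ± 0.15), and xylA, the xylose isomerase gene (3.67 ± 0.11). Also higher were yneB (2.97 ± 0.20) and yneA (2.45 ± 0.19). The sizes for xynB and xylA are uncertain because a probe of each was near background without xylose. The size and rank of xylB depend on the reference, which changed by -1.49 in Cy3. In Cy5 alone xylB rose by 3.25, xynB by 3.27 and ptsG by 4.13. Among the falls were ythB (-2.20 ± 0.25), yxjC (-1.93 ± 0.20), ycgB (-1.69 ± 0.21) and xynA, a secreted xylanase gene (-1.47 ± 0.19), whose probes were near background with xylose, so that the sizes and order of these falls are uncertain. Of 4050 genes tested, 26 passed an adjusted p of 0.05 in limma, 19 of them higher and 7 lower with xylose.

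Outside the xylose and LexA lists, the rises were those of ptsG, msmE (1.53), yqaP of the skin element (0.94), proJ, a proline synthesis gene (0.87), yydF (0.77) and brnQ, a branched-chain amino acid transporter gene (0.71). The last 3 were named after their values were seen. The other falls were those of yubC (-0.80), yfjB (-0.78) and yfjA (-0.73). For ptsG the mean log2 ratio went from -3.04 ± 0.10 (SD, n = 3) without xylose to 1.43 ± 0.20 (SD, n = 3) with xylose, a 22.2-fold rise with a limma adjusted p of 1.98e-05. The probes of ythB, yxjC, ycgB and xynA were above background in Cy5 on 2, 1, 1 and 1 of 3 xylose arrays, and on all no-xylose arrays, and in Cy3 each was above background on 3 of 6 arrays. In all 26 genes the 3 values of one group lay beyond those of the other, as they did in 914 of 4050 genes (22.6%), where chance gives 10%. At an unadjusted p under 0.05 in limma there were 582 genes in the ratio, 675 in Cy5 alone and 744 in Cy3, the pooled reference. The reference thus gave as large a count, so the 582 genes do not by themselves show a response to xylose. Place on the slide went with the group.

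The count was lower whichever array was left out, where fewer arrays enter the fit. It was 14, 16 and 10 without no-xylose replicate 1, 2 or 3, and 9, 10 and 19 without xylose replicate 1, 2 or 3. Of the 26 genes, 9 (ptsG, xylA, xylB, xylR, xynB, dinB, yhaZ, yneA and yneB) passed whichever array was left out. The count was 10 with a replicate block. It was 49 with median centring in place of loess, 50 with a trended robust variance, and 15 in the Cy5 channel alone, which kept 10 of the 19 rises. Of the 7 falls 0 passed in Cy5 alone by limma (smallest adjusted p 0.0506, log2 changes of -0.61 to -1.63), while all 7 had an unadjusted p under 0.05 there.

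**Figure D1:**
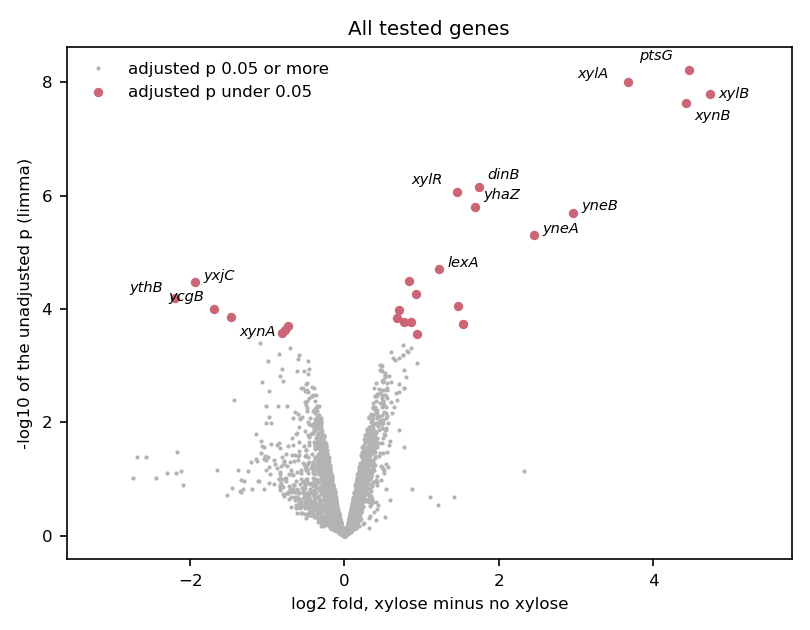
Each point is 1 of the 4050 tested genes, with the log2 fold (xylose minus no xylose, 3 arrays each) on the horizontal axis and -log10 of the unadjusted limma p on the vertical axis. Red points are the 26 genes past an adjusted p of 0.05, with ptsG, xylB, xynB and xylA at the upper right and ythB, yxjC, ycgB and xynA on the left.

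Genes of xylose utilisation tell whether the arrays labelled with xylose came from cells that had received the inducer. Of the 5 genes measured, 4 rose, namely xylB (26.6-fold), xynB, xylA and xylR, the gene of the xylose repressor (2.76-fold), with limma adjusted p-values of 2.16e-05, 2.35e-05, 1.98e-05 and 0.000588. All 3 xylose arrays lay above all 3 no-xylose arrays for each of these genes. The transporter gene xynP had a log2 fold of 0.03 (limma adjusted p 0.908), and its probe was above background on none of the 6 arrays. Adjusted over the list alone, 4 genes rose and 0 fell in limma, as at an unadjusted p under 0.05. The list passed camera with an adjusted p of 8.78e-12, and its call was lost with an estimated correlation (adjusted p = 0.118), the highest of 4.57e-14 to 0.118 over the alternatives.

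The size of the xynB rise is uncertain, as its probe was above background in Cy5 on 1 of 3 no-xylose arrays. So is that of xylA, whose 2 probes differed. The probe with a log2 fold of 5.97 was above background in Cy5 on 1 of 3 no-xylose and 2 of 3 xylose arrays, and the probe with 1.37 on all 6. The Cy3 signal of the pooled reference changed as well, with a fall in xylB of -1.49 (limma adjusted p 0.0457), while changes of -1.16 for xynB and -0.80 for xylA did not pass. The size of the xylB rise in the ratio thus depends in part on the reference. In Cy5 alone, the rises were 3.25 for xylB, 3.27 for xynB, 2.87 for xylA and 1.35 for xylR, and all 4 passed (limma adjusted p 0.00479, 0.000205, 0.000742 and 0.0211).

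The LexA (SOS) regulon, the genes repressed by LexA until DNA damage, was compared because endonuclease cuts break DNA. Of 44 measured members, 9 rose, 0 fell and 35 did not pass the threshold over all genes in limma, and at an unadjusted p under 0.05 there were 21 higher and 2 lower. The rises were those of yneB, yneA, a gene of a cell division inhibitor, dinB (log2 fold 1.75 ± 0.10, SE), yhaZ (1.69 ± 0.11), yhjD (1.47 ± 0.18), lexA, the gene of the repressor itself (1.23 ± 0.12), recA, the recombinase gene (0.93 ± 0.10), uvrA, a nucleotide excision repair gene (0.84 ± 0.09), and ydiP (0.69 ± 0.09). The yneB transcript rose 7.81-fold, yneA 5.47-fold, lexA 2.34-fold and recA 1.91-fold. The median log2 fold of the list was 0.27, with 33 of 44 members above 0.

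Adjusted over the list alone, 20 members were higher and 1, pcrB, was lower with a log2 fold of -0.29 (pcrB was named after its value was seen). The Holliday junction gene ruvA had a log2 fold of 0.49 ± 0.12 (SE, limma adjusted p 0.167 over all genes), and uvrB and xkdA were not measured because their spots were marked as bad. The LexA regulon passed camera with an adjusted p of 3.52e-11. With an estimated correlation its adjusted p was 0.0238. That was the highest of 1.13e-11 to 0.0238 over the alternatives that change 1 choice, apart from leaving out its prophage members. Leaving those members out gave a median of 0.33, with a camera p of 6.38e-14 that was not adjusted over the lists. In the Cy5 channel alone the list median was 0.27 (camera adjusted p 5.62e-05; adjusted p = 0.0582 with an estimated correlation), and 5 members passed, namely dinB, lexA, yhaZ, yneA and yneB, while yhjD (1.49), recA (0.36), uvrA (0.31) and ydiP (0.13) did not. The Cy3 reference changed by -0.57 for recA, -0.53 for uvrA and -0.56 for ydiP, none of which passed. With 1 array left out, 6, 5 and 5 members rose without no-xylose replicate 1, 2 or 3, and 4, 4 and 8 without xylose replicate 1, 2 or 3. The rises of dinB, yhaZ, yneA and yneB passed each time, that of lexA was lost without xylose replicate 1 or 2, and those of recA and yhjD passed only without xylose replicate 3. The rise of uvrA passed only without no-xylose replicate 1 or xylose replicate 3, and that of ydiP was lost whichever array was left out. With all arrays and a replicate block, 3 members rose past the threshold.

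**Figure D2:**
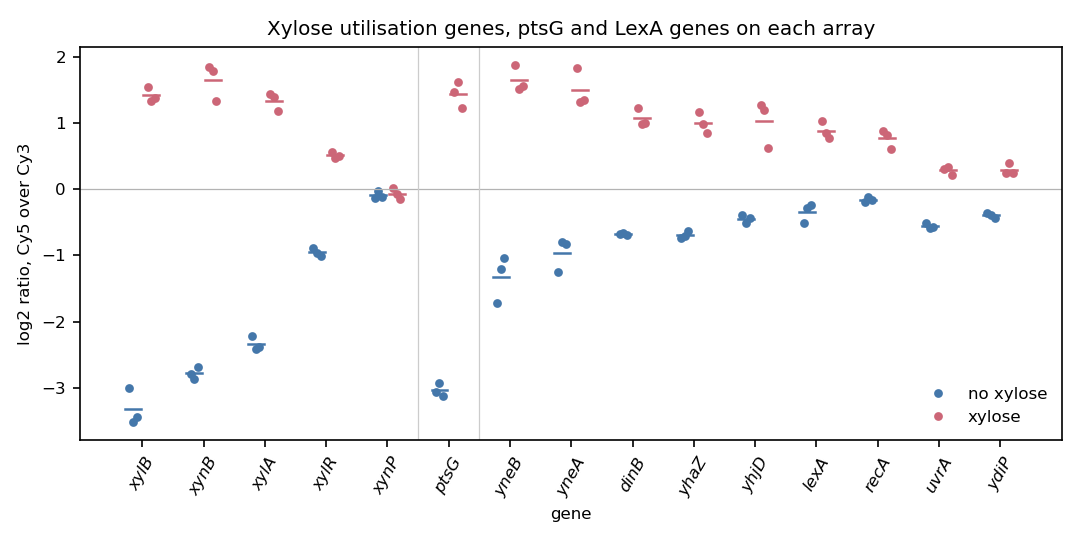
Each point is the log2 ratio of sample (Cy5) over pooled reference (Cy3) on 1 array for the 5 xylose utilisation genes, ptsG and the 9 LexA genes past the threshold, and lines are means of 3 arrays, blue without and red with xylose. The groups overlap only in xynP, whose probe was not above background.

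Across all 21 lists, camera with its preset correlation called the LexA regulon, xylose utilisation and the ribosomal proteins higher than the other genes, and the SPbeta prophage and pyrimidine synthesis lower. With an estimated correlation only the LexA regulon held, and the adjusted p was 0.118 for xylose utilisation, 0.139 for ribosomal proteins, 0.52 for pyrimidine synthesis and 0.937 for SPbeta. This option changes more than the correlation. The LexA list had an estimated correlation of -0.00136, under the preset 0.01, yet its unadjusted camera p went from 3.35e-12 to 0.00113. The lost calls therefore do not show that correlation between genes alone undid them. Ribosomal protein genes had a median log2 fold of 0.22, with 51 of 52 members above 0. In limma 0 passed over all genes, 6 were higher adjusted over the list alone and 17 had an unadjusted p under 0.05, and the members with the smallest p were rpmJ (0.61), rpmB (0.76), rplL (0.47) and rplT (0.49). Pyrimidine synthesis had a median of -0.30 over 12 genes, 0 of them past the threshold in limma over all genes or adjusted over the list alone and 3 with an unadjusted p under 0.05, with pyrH (-0.26), pyrD (-0.64), pyrR (-0.23) and pyrG (-0.31) at the smallest p. The SPbeta prophage, a resident phage genome, had a median of -0.43 over 168 genes, 0 of which passed either way in limma. An unadjusted p under 0.05 was found for 12 of them (3 higher and 9 lower), a smaller share than the 582 of 4050 over all genes. The smallest p were those of yokB (0.75), yokF (0.67), yolB (-0.50) and yoqW (-0.29).

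Camera with the preset correlation gave these 3 lists adjusted p-values of 1.74e-10 (ribosomal proteins), 0.000802 (pyrimidine synthesis) and 6.85e-06 (SPbeta). Over all alternatives the adjusted p was 1.78e-28 to 0.158 for ribosomal proteins, 8.6e-05 to 0.52 for pyrimidine synthesis and 2.23e-15 to 0.937 for SPbeta. By fry, which asks whether the genes of a list move one way on balance, the LexA, xylose and ribosomal lists passed. The SPbeta median was 0.91 on no-xylose replicate 1 and 0.35 on xylose replicate 3, against -0.11 and -0.12 on the other no-xylose arrays and -0.52 and -0.55 on the other xylose arrays. The difference was -0.10 without no-xylose replicate 1 (camera adjusted p 0.377), -0.25 without xylose replicate 2 (camera adjusted p 0.0584) and -0.77 without xylose replicate 3 (camera adjusted p 2.23e-15). It was -0.61 without no-xylose replicate 2 or 3, -0.30 without xylose replicate 1, and -0.40 without both no-xylose replicate 1 and xylose replicate 3 (camera adjusted p 5.94e-14). In the Cy5 channel alone the SPbeta median was 0.05 (camera adjusted p 0.514), while in the Cy3 reference it was 0.45 (camera adjusted p 2.31e-06; adjusted p = 0.319 with an estimated correlation). The pyrimidine synthesis median was 0.70 on no-xylose replicate 1, against 0.27 and 0.20 on the other no-xylose arrays and -0.03, 0.13 and -0.01 on the xylose arrays, and its difference was -0.22 without that array (camera adjusted p 0.00342). With median centring the median fold was 0.43 for ribosomal proteins and -0.19 for pyrimidine synthesis. Ribosomal protein genes past the threshold over all genes numbered 4 with median centring, 4 with trended robust variance and 2 without dim genes. Ribosomal protein genes had a median of 0.11 in Cy5 (camera adjusted p 0.158) and -0.11 in Cy3 (camera adjusted p 0.0414; adjusted p = 0.832 with an estimated correlation). Pyrimidine synthesis had -0.29 in Cy5 (camera adjusted p 0.00834; adjusted p = 0.672 with an estimated correlation).

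The other 16 lists did not pass camera (adjusted p 0.142 to 0.934). Among repair and replication genes, recombination and repair outside the LexA list had a median log2 fold of 0.03 over 28 genes, ribonucleotide reductase -0.07 over 4, the DnaA regulon -0.17 over 12 and cell division -0.06 over 16. In the DnaA regulon thdF (-0.30) and sda (-0.27) had the smallest p, and in cell division ylmF (0.46) did. The PBSX prophage had a median of 0.07 over 31 genes, the ICEBs1 element -0.18 over 23 and the skin element -0.04 over 57, with yqaP as its 1 member that rose. In Cy5 alone the skin element turned to 0.14 and passed camera (adjusted p 0.0395; adjusted p = 0.298 with an estimated correlation). Genes of arabinose utilisation had a median of 0.07 over 12 genes and genes under carbon catabolite control -0.02 over 46. In the catabolite list dctP (-0.84) and acoR (-0.60) were lower adjusted over the list alone and did not pass over all genes (limma adjusted p 0.0707 and 0.0759). Likewise spo0A, the gene of the sporulation master regulator (-0.45), was lower and ylmF of the cell division list was higher adjusted over the list alone, and neither passed over all genes (limma adjusted p 0.0916 and 0.0865). The medians were -0.12 for purine synthesis, -0.07 for competence, 0.03 for motility and chemotaxis, 0.09 for SigB general stress, 0.01 for heat shock, -0.03 for early sporulation and -0.01 for respiration and ATP synthase. Median and camera direction differed in sign for the skin element, cell division and respiration lists, and median and mean for cell division and early sporulation. Single arrays moved 4 of these lists past the threshold. SigB general stress had 0.29 without xylose replicate 1 (camera adjusted p 1.14e-07), and -0.05 and -0.01 without xylose replicate 2 or 3, which did not pass. The ICEBs1 element passed with -0.38 and -0.32 without no-xylose replicate 2 or 3 and with -0.38 without xylose replicate 3 (camera adjusted p 0.011, 0.032 and 0.00649). Purine synthesis passed with -0.19 without no-xylose replicate 1 (camera adjusted p 0.0104), and the PBSX prophage with 0.10 without no-xylose replicate 3 (camera adjusted p 0.0236). These calls rest on the preset correlation, and with an estimated correlation and all arrays the adjusted p of each of these 4 lists was 0.937. With all arrays and the preset correlation, ICEBs1 passed without background correction (camera adjusted p 0.0367), and purine synthesis with print-tip loess (camera adjusted p 0.0218) and with array weights (camera adjusted p 0.0216). With median centring 8 lists passed, among them ICEBs1, arabinose utilisation and motility. With the authors' log2 ratios 11 passed, among them the same 3 lists, SigB general stress, heat shock and cell division.

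**Figure D3:**
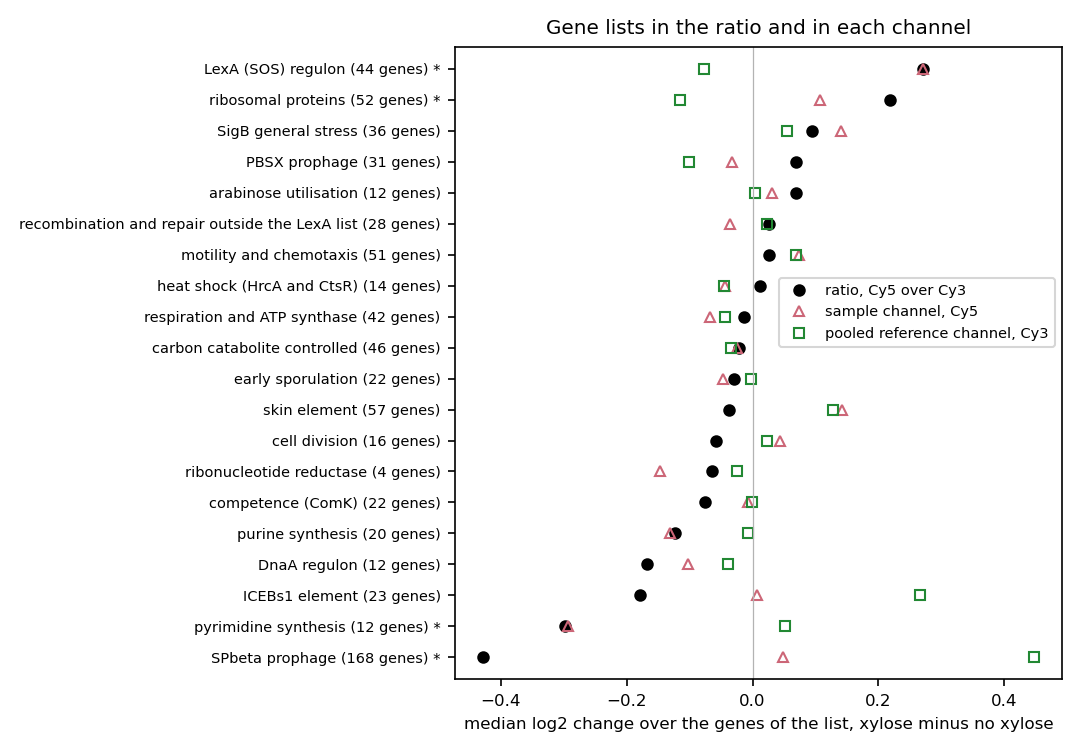
Each row is a gene list other than xylose utilisation, and the horizontal axis is the median log2 change of its genes, xylose minus no xylose, in the ratio (black circles), in the sample channel Cy5 (red triangles) and in the pooled reference channel Cy3 (green squares), with asterisks for lists past camera in the ratio. The SPbeta list lies at -0.43 in the ratio, at 0.05 in Cy5 and at 0.45 in Cy3, while the LexA list lies at 0.27 in the ratio and in Cy5.

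The place of genes along the chromosome was examined because breaks can change gene dosage from the replication origin to the terminus. Across 2974 genes, which are not independent replicates, the log2 fold and the distance from dnaA had a Pearson r of -0.01. The median log2 fold was -0.02 in the fifth of genes nearest to dnaA and -0.03 in the fifth farthest from it. The slope of the log2 ratio from origin to terminus was 0.30 on no-xylose replicate 1 and on xylose replicate 3, and -0.02 to 0.06 on the other 4 arrays. The mean slope differed by -0.01 between groups (exact two-sided permutation p 0.9, n = 3 per group, where 0.1 is the smallest p possible). Positions were known for 73.4% of genes, and break sites were not analysed here.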

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

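The tests in this part were chosen after the results were seen. The comparisons of genes left out the probes of intergenic regions, and 263 of these were tested by themselves with limma. In 6 of them the signal was above that of the no-xylose arrays past an adjusted p of 0.05, in 2 it was lower, and 38 had an unadjusted p under 0.05. The probe between xylB and yncB, next to the xylose operon, had a log2 fold of 6.36 (limma adjusted p 3.82e-09), and that between yncB and yncC 1.30 (limma adjusted p 0.003). The probe between ynaI and xynP had 2.73 (limma adjusted p 3.21e-05), while the xynP probe itself was not above background. The probe between aprX and ymaC had 1.55 (limma adjusted p 0.00706) and that between ykvQ and ykvR 0.61 (limma adjusted p 0.0348), where aprX and ykvR are members of the LexA list that did not pass, with log2 folds of 0.17 and 0.26, and ymaC, with 2.33, did not pass either. The probe between cydA and yxkJ had 0.65 (limma adjusted p 0.0348). All 6 probes were above background in Cy5 on all 6 arrays.

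Dixon's test for outlying arrays was not run, since it is not used here for groups of 3.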

How the results depend on the processing

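The Cy5 channel alone, leaving out not-found spots, testing each probe by itself, and leaving out no-xylose replicate 1 with xylose replicate 3 were chosen after seeing the data. All 26 genes kept their direction under every alternative that tested them. For part of the alternatives this was fixed in advance, since genes whose groups do not overlap keep their direction with any array left out. The trended variance and the replicate block leave the fold unchanged. The number of genes past the threshold was 49 (38 higher, 11 lower) with median centring, 50 (34 and 16) with trended robust variance, 15 in Cy5 alone, and 9 to 19 with 1 array left out, where fewer arrays enter. Other alternatives gave 21 to 38 apart from the block. With a replicate block it was 10, all among the 26 and 3 of them LexA members, and ICEBs1 passed camera with the preset correlation (adjusted p 0.0446). With an estimated correlation and no block the camera adjusted p of ICEBs1 was 0.937. Deviations of same-numbered arrays correlated at -0.238, 0.274 and -0.268, and 1 of 3 arrays correlated best with its own number. Deviations from a mean of 3 arrays are tied to each other, so this check could hardly show pairing. Same-numbered arrays were scanned in succession, with Cy5 scanner voltages of 610 and 600, 600 and 590, and 640 and 630. No label pairs the arrays, so the main fit has no block, but pairing is not excluded. The 4 xylose genes passed in every setting. The LexA regulon median was 0.04 to 0.34 and passed in each single alternative, but not in Cy5 alone with an estimated correlation (adjusted p 0.0582), the lowest with the authors' log2 ratios, whose median over all genes was -0.17 (0.20 relative to it). The number of lists was 8 with median centring, 11 with the authors' log2 ratios, 1 with an estimated correlation, 3 with fry, and 4 to 7 with 1 array left out. The SPbeta median turned to 0.0488 in Cy5 alone. The Cy5 signal was still normalized together with Cy3. Without division by the reference it also carries any difference in the amount of probe on the spots. The slope difference for position along the chromosome, never called, turned to 0.0070 without background correction, 0.0051 with scaling, 0.101 without dim genes, 0.0079 without not-found spots and 0.157 in Cy5 alone, and was -0.104 to 0.077 with 1 array left out. For the other moves the cause was not tested. Requiring a value on all arrays removed no gene. Folds of genes whose probes were near background, such as xynP and ythB, are uncertain in size.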

Other observations

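The tests in this part were chosen after the results were seen. On the xylose replicate 3 array, genes of iron uptake under the Fur repressor were far lower than on the other xylose arrays. The list of 38 genes was compiled from general knowledge after some of these genes had been seen to be low, so its counts are no independent evidence. Of its genes, 36 were lower than on both other xylose arrays and 31 by 1 log2 unit or more, among them the flavodoxin gene ykuN (-5.51), ykuP (-4.88), yxeB (-4.64), the bacillibactin synthesis genes dhbA (-4.20), dhbE (-4.09) and dhbC (-3.90), and the ferrichrome gene fhuD (-4.03). Of the 30 genes that were lowest on that array relative to the other xylose arrays, 26 were in the list. The list median was 0.73, 0.64 and 0.58 on the no-xylose arrays and 0.22, 0.05 and -2.08 on the xylose arrays, a median difference of -0.52 between the other xylose arrays and the no-xylose arrays. In the comparison of groups 0 of the 38 genes passed in limma, while 15 were lower at an unadjusted p under 0.05.

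The fall on xylose replicate 3 lay in the sample channel, with a median change of -2.38 in the ratio and -2.26 in Cy5, while the Cy3 reference changed by 0.15, which argues against a reference that differed on that array. Poor detection is argued against by 94.7% of members being above background in both channels on all other 5 arrays. A no-xylose sample under a xylose label is argued against by the 12 LexA and xylose genes that passed in the fit without that array. Their median rise over the no-xylose mean was 1.61 on that array, against 1.77 on the other xylose arrays, and all 12 lay above every no-xylose array there. What stays open is a difference of that culture or sample, and no biological explanation was tested, since the labels name no group to set it against.

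The Cy3 channel holds the pooled reference, yet 18 genes differed in Cy3 between the groups in limma (13 higher and 5 lower with xylose), 7 of them SPbeta genes. Of these, 15 moved the same way in Cy5 by at least 0.5 times as much, such as yndB (-2.89 in Cy3, -2.60 in Cy5) and yomW (3.09 and 2.48). Different amounts of probe on the spots would give this, and place on the slide goes with the group. However, most genes changed little in the ratio, so genes picked for a large Cy3 change tend to move alike in Cy5. The share over other genes was not taken, so the count cannot decide on the amount of probe. The xylose genes moved apart instead, xylB by -1.49 in Cy3 and 3.25 in Cy5. Displacement of reference by the sample's own RNA was looked at in the 10 other called genes with a Cy5 rise of 1 or more. Their median Cy3 change was -0.056. The lowest of them was that of ptsG, -0.34 with a Cy5 rise of 4.13, which goes the way that displacement would. The called rises under this cut were recA (-0.57 in Cy3), ydiP (-0.56), uvrA (-0.53), brnQ (-0.33) and yydF (0.003). The Cy3 change is the Cy5 change less the ratio change, so the cut on Cy5 selects against falls in Cy3. This test therefore cannot decide on displacement. A reference RNA that differed between the groups of arrays cannot be told apart from the groups, since 0 arrays were scanned at the end that holds the other group. The real split of the arrays gave 18 genes in Cy3 and the highest of the other splits 1, with 1 of 10 splits as large, too few for a share under 0.05.

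For the SPbeta list the ratio median was -0.43 and the Cy5 median 0.05. The Cy3 median was 0.45 (camera adjusted p = 0.319 with an estimated correlation). The lower ratio may come from a change in the reference channel, or from less sample RNA on spots that held more probe. The channels cannot tell these apart, since the amount of probe enters both. Dim probes in general are argued against by 10000 random lists matched on intensity, whose lowest median was -0.083. Of these lists 0 reached -0.43, although such lists lack the correlation of 0.566 between SPbeta genes. Without the dimmest genes the list kept a median of -0.40 over 40 members, and its call was lost (camera adjusted p 0.134), with fewer genes in the list. An effect of xylose or of the endonuclease on the prophage stays open and untested.

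Intergenic probes may report transcripts that extend from a neighbouring gene. Across 261 intergenic probes without a xylose gene beside them, the log2 fold of the probe went with the mean log2 fold of the flanking genes (Spearman rho 0.374, Pearson r 0.367, two-sided permutation p 1e-05, the smallest that the permutations can give), where probes are not independent replicates.

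The 6 arrays can be split into groups of 3 in 10 ways, too few for a share under 0.05. The real split called 26 genes and the highest of the other splits 0, so that 1 split was as large. The LexA median was 0.27 for the real split and at most 0.165 in size for the others, again with 1 split as large. The number of lists past camera was 5 for the real split, while 8 of the 10 splits gave as many and the highest of the others gave 9.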
